A study of Mus musculus with 3 samples.

How the data were processed

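Mouse E14 embryonic stem cells kept with 10 µM T0901317 were aggregated in microwells and harvested on day 5, per the labels. For all 3 libraries the labels also give 12.5 ng/mL rhFGF4, 5 ng/mL BMP4, 0.5 µM A83-01 and 3 µM CHIR99021. They further give 2 µM Y27632 and 0.5 µg/mL heparin. Blastoids were digested for 30 min, and libraries were made with the 10x Chromium 3' kit v3.1, per the labels. The values used are UMI counts per gene and barcode, made with Cell Ranger 6.0.1 per the file headers, on build mm10 per the submitters' processing notes, and deposited as 1 matrix of 32285 genes for each of 3 libraries. How barcodes were called as cells is not given in the sources used here. No reads were used here.

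Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. Scrublet's own threshold called 0, 0 and 2 doublets, so the highest scores up to a loading rate of 0.8% per 1000 cells were removed instead (223, 556 and 11 barcodes). These were mostly shallow barcodes, so doublets are not reliably removed. Counts were scaled to 10000 per cell and logged, and the 3 libraries were clustered together with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Genes of the fixed lists tested between classes were kept out of the clustering. The lineage genes whose UMI shares are given, such as Nanog, Gata6 and Krt8, were not kept out, so their shares describe the classes and do not test them. A cluster was named for a cell type when at least 3 of its markers had a log2 fold above 1 over the other cells and were detected in at least 10% of its cells, taking the type with the highest mean fold. It stayed unnamed where another type had more markers among its top 10 genes, or where it was much shallower than its library and had no marker there. The limits used in naming, the division at 10000 UMIs, equal cluster weights and most tests of technical explanations were chosen after the data were seen. Filters, markers, gene lists and the comparisons with their tests were chosen before the data were examined.

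Shares of cells have exact 95% binomial intervals. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, and a share of 0 is given with the upper limit that a count of 0 allows. Libraries were compared by counts summed over cells, in CPM (counts scaled to the same total in each library) with 10 CPM added. Because each type has 1 library, no p-value was computed between types. A gene is called higher or lower at 2-fold or more with at least 50 CPM in 1 of the 2 libraries. Intervals cover counting error only. A list stands apart when its median log2 ratio lies below percentile 2.5 or above 97.5 of 10000 random lists matched on expression. Within a class, both libraries needed at least 50 cells.

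Classes were compared with edgeR 4.0.16 quasi-likelihood tests on counts summed per library and class, with library as a block, TMM scaling and Benjamini-Hochberg adjustment over 13378 genes at 0.05. The common dispersion was 0.00615. Only genes of the fixed lists are reported. Lists were tested with camera, at a preset correlation of 0.01 and with an estimated one, and with fry (limma 3.58.1). Named genes are those with the 5 highest and 5 lowest ratios of each pair of libraries, leaving out mitochondrial, ribosomal, Xist, Y and unnamed transcript genes, up to 4 members of each list that stands apart, and up to 4 members of each list in the class comparisons, besides the fixed lineage genes. Leading genes of clusters are among the top 10. Some genes that meet these rules are not reported here. Of the listed symbols 7 were not measured, 5 absent from the files and 2 with more than 1 gene.

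With simulated counts the class test found 75.0% and 77.0% of genes changed 1.5-fold and all of those changed 2-fold, with 7, 0 and 11 false calls among 12724 genes. Here all classes had the EPI-like means, with 200 genes changed in PrE-like sums and a dispersion of 0.01. In the data most genes differed between classes, so these rates may not hold for the real comparisons. The size rule found all genes changed 3-fold and none changed 1.5-fold. There 25 and 24 lists were measured, the planted list included, and besides it 1 and 3 lists stood apart. These simulated counts had Poisson error only, so they do not show how many lists stand apart between real libraries without a difference of type. Transcript ends were searched for near-identical copies elsewhere in the annotated transcripts in windows of 50 bases, and a gene with matches in at least 20% of windows has an uncertain level.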

Results

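Single-cell RNA-seq was run on mouse blastoids, which are embryo-like structures grown from stem cells that resemble the blastocyst. The source cells were E14 embryonic stem cells kept with T0901317, a small molecule that activates the liver X receptors, one of which is encoded by Nr1h2. Blastoids were picked by hand on day 5. There were 3 libraries, titled NrESC_Type_I, NrESC_Type_II and NrESC_Type_III, here Type I, Type II and Type III. Each type had 1 library, so differences between types have no replicate check. What sets the types apart is not given in the labels. Genes are named by the symbols the files pair with their Ensembl identifiers.

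The deposited matrices held 6813 barcodes and 90126648 UMIs for Type I, 9265 barcodes and 106445641 UMIs for Type II, and 2310 barcodes and 25443474 UMIs for Type III. Filtering and doublet removal kept 5051, 7780 and 1179 barcodes. Most kept barcodes were shallow, with median UMI counts of 2376, 2214 and 2502. Barcodes with at least 10000 UMIs made up 27.5%, 25.4% and 23.1% of those kept, and in the deposited matrices such barcodes held 87.1%, 82.9% and 83.8% of all UMIs. Expression summed over cells therefore describes mainly the deep barcodes, and shares of barcodes describe mainly the shallow ones.

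The study asks about the transcriptomes of the lineages in the blastoid. Clusters named by markers for each of the 3 blastocyst lineages were found in all 3 libraries. EPI-like cells formed cluster 5, which was shallow, and cluster 7, which was deep. Both were led by the pluripotency genes Klf2, Zfp42 and Nanog. PrE-like cells formed cluster 2, led by the visceral endoderm secretory genes Apob, Apoc2, Ttr and Rbp4, and cluster 10, led by the basement membrane gene Lama1, the endoderm regulator Gata6 and Htra1, a secreted protease. TE-like cells formed cluster 3, led by the homeobox genes Rhox6 and Rhox9 and the trophoblast regulator Gata2, and cluster 8, led by the epithelial genes Krt19 and Sfn and by the annexin gene Anxa1. Post-implantation states were also present: a primed epiblast-like cluster with Nodal, Otx2 and Pou3f1, a streak mesoderm-like cluster with Fgf8 and T in which the interferon and immunoproteasome genes Isg15, Psmb8 and Gbp2b were also among the leading genes, and 45 blood or endothelial-like cells with Cdh5, Kdr and Hbb-bh1. A further 34 cells were 2C-like, a state marked by genes of the embryo at the 2-cell stage.

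PrE-like cells were 14.0% of Type I (95% interval 13.1% to 15.0%), 11.9% of Type II (11.2% to 12.6%) and 4.75% of Type III (3.61% to 6.12%). EPI-like cells were 8.73%, 11.1% and 16.1%, and TE-like cells 12.9%, 8.88% and 24.6%. Type III therefore held the lowest PrE-like share and the highest shares of the other 2 lineages, with intervals that did not overlap those of Types I and II. Primed epiblast-like cells were 4.02%, 4.63% and 4.41%, streak mesoderm-like cells 4.40%, 2.79% and 1.10%, and 2C-like cells 0.0990%, 0.270% and 0.679%. The shares of these rarer states depend on the processing. Streak mesoderm-like cells were 1.41% of Type I and 1.504% of Type II at resolution 0.5, and 0.653% and 0.938% with 4000 variable genes, so the order of Types I and II is not kept. The 2C-like share was 1.13%, 1.48% and 4.02% with a strict filter (at least 1000 genes, at least 3000 UMIs, at most 10% mitochondrial UMIs). With that filter the primed epiblast-like share was 8.455%, 10.95% and 9.091%, but at resolution 0.5 it was 0% in all 3 libraries. When barcodes with at least 10000 UMIs were clustered on their own no cluster was named 2C-like, but an unnamed cluster of 57, 148 and 23 barcodes shared its leading genes Gm21761, Gm8994 and Gm20767. Barcodes in clusters that met no naming rule were 55.4%, 60.2% and 47.8%, and nearly all of them were shallow. Unnamed cluster 0 held 20.2%, 34.6% and 14.4% of the libraries, cluster 1 held 19.4%, 17.1% and 20.6%, and cluster 4 held 12.5%, 5.15% and 5.43%. All 3 were led by AY036118 and Gm42418, transcripts that overlap ribosomal RNA sequence, at median UMI counts of 1367, 2377.5 and 1796. Whether these barcodes are damaged cells or empty droplets was not tested, and shares of barcodes depend on them. The PrE genes Sox17 and Lgals2 were also among the leading genes of cluster 1, and Apob among those of cluster 4. Among barcodes with at least 10000 UMIs, the PrE-like share was 47.6%, 44.4% and 17.6%, the EPI-like share 14.8%, 17.5% and 29.8%, and the TE-like share 17.8%, 15.7% and 28.3%. When each library was clustered alone and all its barcodes were counted, the PrE-like share of Type III was 37.8% against 14.4% and 12.2%, which reverses the order. The order returned when only its deep barcodes were counted (47.6%, 44.5% and 20.2%).

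**Figure D1:**
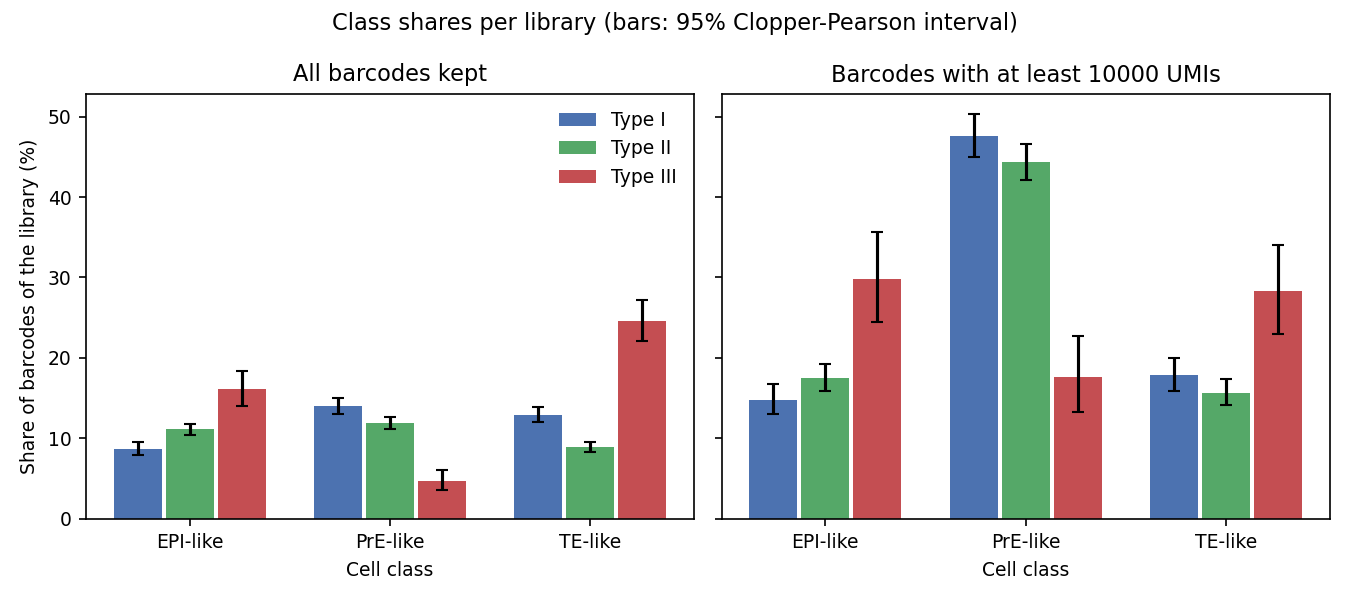
Share of barcodes per library, in percent, in the EPI-like, PrE-like and TE-like classes, for all kept barcodes (left) and for barcodes with at least 10000 UMIs (right); bars on the columns are exact 95% binomial intervals for counting error. The PrE-like share of Type III is 4.75% on the left and 17.6% on the right, below the other 2 libraries in both panels.

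Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs. Nanog, a core pluripotency factor, was detected in 26.2%, 23.1% and 34.8% of EPI-like cells of Types I, II and III, against 0.141%, 0.650% and 5.45% of PrE-like and 1.35%, 2.38% and 1.92% of TE-like cells. Pou5f1 was detected in 57.4%, 50.0% and 64.6% of EPI-like cells, Sox2 in 28.1%, 27.9% and 25.3%. The endoderm factors Gata6, Sox17 and Gata4 were detected in 18.6%, 23.4% and 17.7% of PrE-like cells of Type I, against 0.557%, 2.23% and 1.11% of its EPI-like cells. Krt8, a keratin of the trophectoderm, was detected in 76.0%, 83.2% and 89.1% of TE-like cells, but also in 57.6%, 53.9% and 49.1% of PrE-like cells. Gata3 was detected in 8.52%, 6.95% and 7.05% of TE-like cells and in none of the PrE-like cells, which allows up to 0.424%, 0.325% and 5.45%. Cdx2, the trophectoderm specifier, was at the PrE-like background, with 2.69%, 2.74% and 2.56% of TE-like cells against 2.12% and 1.62% of PrE-like cells in Types I and II. Streak mesoderm-like cells had more of it, with 10.98% and 8.20%. The trophoblast stem cell genes were rarer still: over the 3 libraries Eomes was found in 0.435% of TE-like, 0.395% of EPI-like and 1.66% of PrE-like cells, and Elf5 in 2 of 1149 TE-like cells. Without thinning, Cdx2 was found in 12.3%, 9.32% and 6.41% of TE-like cells and in 38.8%, 24.8% and 23.6% of PrE-like cells, whose median UMI counts were 51760, 39180 and 91430 against 16460, 20900 and 9097. Zscan4c, which marks the 2C-like state, was found in 5 of 28 2C-like cells over the 3 libraries (17.9%) and in no EPI-like, PrE-like or TE-like cell, which allows up to 0.237%, 0.178% and 0.261%. After thinning, pairs of opposing lineage genes (Nanog with Gata6, Pou5f1 with Cdx2, Gata6 with Cdx2) met in at most 1.82% of cells of any of the 3 lineages. At that depth the single genes are often missed, as for Cdx2 in PrE-like cells of Type I (2.12% against 38.8% without thinning). The low pair shares therefore do not show that these genes are rarely expressed together. Thinning left out cells under 2000 UMIs: 82, 114 and 32 EPI-like, 0, 0 and 1 PrE-like, and 208, 144 and 134 TE-like cells. The unthinned shares for Nanog and Pou5f1 in EPI-like cells were 66.3%, 57.7% and 64.6%, and 88.9%, 82.8% and 93.7%.

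PrE-like cells were compared with EPI-like cells to ask how the endoderm lineage differs beyond its markers. The receptor gene Nr1h2 was 15.0 ± 1.67 CPM (mean ± SD, n = 3 libraries) in PrE-like and 23.7 ± 1.11 CPM in EPI-like cells, and fell by 0.91 on the log2 scale (SE 0.0942, adjusted p = 1.46e-06). The cholesterol program rose as a whole: 25 of 25 genes of cholesterol synthesis and uptake passed the threshold upward, with a median log2 fold change of 1.32. Camera called this list at the preset correlation (adjusted p = 4.39e-08) but not with an estimated one (adjusted p = 0.2397). Stard4, which carries cholesterol inside the cell, rose by 2.84 (SE 0.0943), Sc5d by 2.57 and Cyp51 by 2.39, both enzymes of the late pathway. Of 12 fatty acid synthesis genes, 11 rose and 1 fell. Elovl1, which lengthens fatty acids, rose by 3.69 and Fasn, the synthase itself, by 1.78. Of 12 LXR targets, 8 rose and 3 fell. Apoe, a lipid carrier secreted by yolk sac endoderm, was 6888 ± 549 CPM against 1025 ± 119 CPM, a log2 rise of 2.54 (SE 0.0727, adjusted p = 1.79e-11). The desaturase gene Scd1 rose by 2.92, and the lipase gene Lpl fell by 3.53.

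Of 16 genes for fluid transport and tight junctions, 13 rose and 1 fell in PrE-like cells (camera adjusted p = 2.22e-08, but adjusted p = 0.2397 with an estimated correlation), among them the water channel gene Aqp8 (5.49), the claudin gene Cldn6 (3.28) and the transporter scaffold gene Slc9a3r1 (2.95). The imprinted growth regulators H19, Dlk1 and Igf2 rose by 3.98, 5.33 and 3.49, and of 27 imprinted genes 17 rose and 8 fell. In the other direction, 15 of 20 S phase genes fell and 2 rose. Ung, a uracil repair enzyme, changed by -2.48 and Hells, a chromatin remodeler of replication, by -1.87. Of 10 genes of the DNA methylation machinery, 7 fell and 1 rose. Dppa3, which keeps the maternal genome methylated, changed by -6.43 and Tet1, which removes methylation, by -2.32, while Tet3 rose by 2.62. Signalling targets were mixed and not called by camera. Per the labels all libraries had added FGF4, BMP4, A83-01 and CHIR99021, and the effect of these additions on the targets was not tested. Of 13 FGF and ERK targets 4 rose (Phlda1 2.84) and 6 fell (Ccnd1 -5.01), of 11 WNT targets 2 rose (Rnf43 1.97) and 6 fell (Lef1 -5.41), and of 11 NODAL and TGFb targets 4 rose and 6 fell (Nodal -4.07). All 20 ribosomal protein genes fell, by a median of 0.72. In this comparison 277 of 329 readout genes passed the threshold, 145 upward and 132 downward, and the count adjusted over the list alone was also 277. Over all 13378 genes tested, 5135 passed upward and 4870 downward, so most genes passed, whether listed or not.

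Imprinted genes had the lowest camera p-value in TE-like over EPI-like cells, and 19 of 27 rose and 3 fell, with a median log2 fold change of 1.47. H19 was 1418 ± 213 CPM against 64.7 ± 19.4 CPM, a log2 rise of 4.04 (SE 0.102, adjusted p = 4.53e-11). The growth factor gene Igf2 rose by 4.46 and Airn, a non-coding RNA that silences a placental gene cluster, by 5.04. Targets of YAP, the transcriptional coactivator that drives trophectoderm fate, rose in 10 of 11 cases. Ccn1 rose by 2.22 and Tgfb2 by 3.76. BMP targets rose in 8 of 10 cases, with Msx2 up by 4.42 and Id2 by 1.57. Of 16 genes for fluid transport and tight junctions 10 rose, among them the polarity gene Pard6b (2.65) and Cldn7 (2.39), and 1 fell, the water channel gene Aqp3 (-2.34). Of 11 epithelial and mesenchymal genes 7 rose and 1 fell, with Dsp, which encodes the desmosome anchor desmoplakin, up by 3.28. Of 19 immediate early and dissociation genes, 13 rose and 3 fell, with Jun up by 2.41 and Fos by 2.31. These genes also respond to tissue digestion. All 20 oxidative phosphorylation genes and all 20 ribosomal protein genes fell, by medians of 0.77 and 0.74. Cox5a, a subunit of the last respiratory complex, changed by -1.05. Of 20 S phase genes 17 fell, with a median of -0.58, but their median log2 ratios in plain CPM were 0.01, -0.17 and -0.14 in the 3 libraries, so this direction depends on the scaling. Nr1h2 changed by -0.95 (SE 0.0975, adjusted p = 2.71e-06). Here 267 readout genes passed, 127 upward and 140 downward, and 269 when adjusted over the list alone. Of all 13378 genes tested, 4040 passed upward and 4259 downward.

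PrE-like cells also exceeded TE-like cells in the cholesterol program, with 24 of 25 genes up and a median log2 fold change of 1.03. By camera the adjusted p was 1.19e-07, but 0.358 with an estimated correlation. Insig1, a sensor that restrains the pathway, rose by 2.41 (SE 0.0787, adjusted p = 5.65e-11) and Stard4 by 1.95. Apoe rose by 3.84 and Lpl changed by -4.64. Of 20 oxidative phosphorylation genes 19 rose, with Uqcrq up by 1.54 and Cox8a by 1.13. BMP targets fell in 8 of 10 cases (Id3 -1.79, Msx2 -2.21) and WNT targets in 8 of 11 (Axin2 -1.58, Lef1 -4.04), while of 13 FGF and ERK targets 4 rose and 4 fell. Of 19 immediate early and dissociation genes 14 fell, with Dusp1 at -2.25. Imprinted genes divided, with 9 up and 14 down in PrE-like cells. The placental growth restrictors Cdkn1c and Phlda2 changed by -5.88 and -3.93 and the amino acid transporter gene Slc38a4 by -4.82. Nr1h2 did not pass (log2 0.04, adjusted p = 0.834). In all 249 readout genes passed, 136 upward and 113 downward, and 252 when adjusted over the list alone. Of all 13378 genes tested, 4532 passed upward and 4322 downward.

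The 3 libraries stand in for replicates in these comparisons of classes although they are different types, so each p-value measures how alike a class difference was across them. TMM scaling moved every log2 fold change from the ratio of plain totals by -0.21 for PrE-like over EPI-like, -0.42 for TE-like over EPI-like and 0.20 for PrE-like over TE-like cells. By camera with a preset correlation, cholesterol synthesis and uptake was called in PrE-like over EPI-like cells (adjusted p = 4.39e-08) and in PrE-like over TE-like cells (1.19e-07). The former was adjusted p = 0.2397 with an estimated correlation and the latter 0.358. LXR targets were called over EPI-like cells (0.0185, and adjusted p = 0.2397 with an estimated correlation) and over TE-like cells (0.0487, and adjusted p = 0.358 with an estimated correlation). The call over TE-like cells was lost in 10 other settings, so it is weak. Imprinted genes in TE-like over EPI-like cells had an adjusted p of 8.18e-12, and this was the only call kept with an estimated correlation, at 0.0270. By fry, which tests net direction, LXR targets had adjusted p-values of 8.37e-05, 0.00289 and 0.000933 in the 3 comparisons in the order above, but camera did not call them in TE-like over EPI-like cells (adjusted p = 0.330), where 6 rose and 3 fell. Fry does not set a list against the other genes, most of which passed in these comparisons. In PrE-like over EPI-like cells fry also called FGF and ERK (adjusted p = 0.0138), WNT (0.00378) and NODAL and TGFb targets (0.00346), which camera did not. The fry values are therefore not particular to LXR targets.

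Whole Type II and Type I libraries were close. Of 2592 genes with at least 50 CPM, 1 was 2-fold or more apart: Phlda2, the imprinted placental growth restrictor, at 23.5 CPM in Type II and 62.7 CPM in Type I (log2 -1.12). The pluripotency co-receptor gene Tdgf1 (0.59), the growth factor binding gene Igfbp2 (0.60) and the lactate exporter gene Slc16a3 (0.55) were higher in Type II by less. In all 15 of 25 lists stood apart from random lists, with medians of 0.33 for EPI markers, 0.21 for glycolysis and -0.18 for parietal endoderm.

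Type III differed from Type I in 40 of 2736 genes, 17 higher and 23 lower. Visceral endoderm genes were lowest: Rbp4, the retinol carrier, was 157 CPM (95% Poisson interval 152 to 162) against 667 CPM (661 to 672), a log2 ratio of -2.02, and Ttr, the thyroid hormone carrier, was 267 against 916 CPM (-1.74). Apoa2 was lower by -1.87 and Cited1 by -1.63. Trophectoderm genes were highest, with Lgals3 at 59.0 against 11.7 CPM (1.67), Sfn at 93.9 against 23.5 CPM (1.63) and the tight junction gene Cldn4 at 81.5 against 21.9 CPM (1.52). Pluripotency genes were higher below the 2-fold rule, with Pou5f1 at 250 against 127 CPM (0.93) and Nanog at 75.7 against 37.0 CPM (0.87). List medians were -1.52 for visceral endoderm, -0.73 for PrE markers, 1.37 for TE markers, 0.75 for EPI markers and 0.42 for glycolysis. Oxidative phosphorylation (-0.27), fluid transport and tight junctions (-0.39) and LXR targets (-0.25) were lower. Sums over whole libraries also follow their makeup. PrE-like cells held 40481426 of 85644086 UMIs in Type I but 5444612 of 23298945 in Type III. By median, LXR targets and fluid transport genes were highest in PrE-like cells, and oxidative phosphorylation genes lowest in TE-like cells. These whole-library medians therefore do not show a change within cells. Against Type II, 14 genes were higher and 11 lower in Type III, led by Cldn4 (1.43), Anxa1 (1.35) and Sfn (1.26) upward and by Apoa2 (-1.80), Ttr (-1.64) and Rbp4 (-1.54) downward. The balance of calls moved with scaling: 11 higher and 28 lower over Type I, and 7 higher and 17 lower over Type II, after TMM scaling, and 11 and 27, and 9 and 16, with DESeq2 size factors. Nr1h2 was 15.9, 18.8 and 19.5 CPM in Types I, II and III, and its log2 ratio of Type III to Type I was 0.19 (interval of the count ratio 0.14 to 0.45).

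Within EPI-like cells no gene was 2-fold apart between Type II and Type I. The shallow cluster 5 held 55.8%, 63.9% and 66.3% of these cells, and Type III over Type II went from 4 genes higher and 2 lower to 4 higher and 11 lower with both clusters weighted equally. Between Type III and Type I, Eno1 (log2 1.17) was higher by this rule, but 83.8% of the 50-base windows searched in its transcript end match a near-identical copy, so its level is uncertain. Spink1, a protease inhibitor of endoderm, was lower (-1.07, 42.0 against 99.2 CPM). Spink1 was 6601 CPM in PrE-like cells of Type I and lower in all 3 classes of Type III (-0.58 in PrE-like and -1.24 in TE-like cells), so endoderm RNA in the droplets was not excluded for it or for the cholesterol genes, which are highest in PrE-like cells. Cholesterol synthesis and uptake had a median of -0.43 over 4 genes, with Fdps, an enzyme of isoprenoid synthesis, at -0.45, and fatty acid synthesis -0.36 over 3 genes. Naive pluripotency genes were higher (0.32), with Nanog at 0.41, and S phase genes slightly higher (0.16). Glycolysis genes were higher (0.38), with the phosphofructokinase genes Pfkl and Pfkp at 0.78 and 0.76.

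Within PrE-like cells Type II and Type I had no gene 2-fold apart, while Type III had 15 genes higher and 6 lower than Type I. Different clusters weigh in here: cluster 10 held 16.7%, 19.9% and 46.4% of PrE-like cells in Types I, II and III, and Type III had only 56 such cells. Ckb, a creatine kinase gene, was 298 against 62.5 CPM (log2 2.09), Htra1 101 against 22.7 CPM (1.76) and Pou5f1 100.1 against 24.1 CPM (1.69). Epas1 (-1.31), which encodes a hypoxia-inducible transcription factor, Rbp4 (-1.13) and Apoa2 (-1.11) were lower. With both clusters weighted equally, 1 gene was higher and 2 lower, the visceral endoderm median went from -0.53 to 0.26 and the imprinted gene median from -0.16 to 0.20. Glycolysis (0.35, and 0.32 with equal weights), cholesterol synthesis (0.24 and 0.26) and fatty acid synthesis (0.24 and 0.22) kept their medians.

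Within TE-like cells Phlda2 was 62.7 CPM in Type II against 296 CPM in Type I (log2 -2.07), or -0.93 with the mean of per-cell CPM, and the hormone gene Sct was higher (1.32). Type III had 22 genes higher and 9 lower than Type I, but 12 and 10 with DESeq2 size factors and 7 and 14 with the mean of per-cell CPM, so the balance depends on the processing. Lgals3, a lectin of the mural trophectoderm, was 142 against 33.9 CPM (1.79), Tagln, an actin binding gene, 115 against 25.4 CPM (1.82) and Sfn 220 against 85.4 CPM (1.27). The trophoblast regulator Ascl2 was higher (1.12), and the pluripotency genes Dppa3 (1.57) and Pou5f1 (1.20) were higher too. The cyclin gene Ccnd2 (-1.40) and the hedgehog receptor gene Ptch1 (-1.17) were lower. TE markers had a median of 0.89, mural trophectoderm genes 0.83 and EPI markers 0.75, and these were 0.79, 0.68 and 0.63 with both clusters weighted equally. Hypoxia genes were higher in Type II (0.46) and in Type III (0.40) than in Type I. Against Type II, Type III was higher in Esx1 (1.22), a placental homeobox gene, and in Phlda2 (1.30, but -0.011 with the mean of per-cell CPM), and lower in Spink1 (-1.44) and Cdkn1c (-1.17). Cluster 3 held 69.0%, 65.0% and 81.0% of TE-like cells, and with equal weights the counts over Type I were 11 higher and 6 lower.

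**Figure D2:**
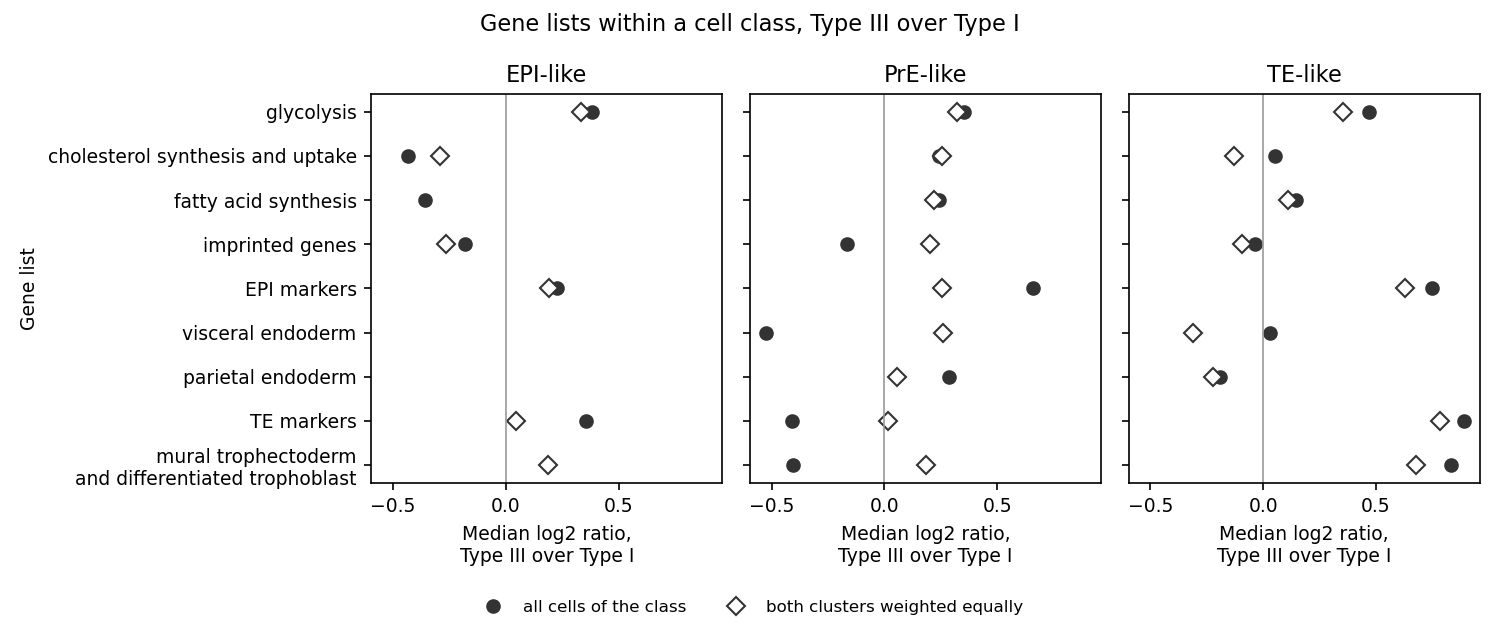
Median log2 ratio of Type III over Type I for gene lists within EPI-like, PrE-like and TE-like cells, with all cells of a class (filled points) and with both clusters weighted equally (open points). Glycolysis lies above 0 in all 3 classes (0.38, 0.35 and 0.47), whereas the visceral endoderm median in PrE-like cells goes from -0.53 to 0.26.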

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

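The tests on shallow barcodes, joint clustering, epiblast RNA, the visceral endoderm mix, genes shifted alike and splits were chosen only after the result was seen.

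Several lists stood apart in opposite directions in different classes, and these differences between classes were not tested. Cholesterol synthesis and uptake in Type III over Type I was 0.24 in PrE-like and -0.43 in EPI-like cells, and fatty acid synthesis was 0.24 and -0.36. TE markers were 0.36 in EPI-like and 0.89 in TE-like cells but -0.41 in PrE-like cells, and over Type II they were 0.41 in TE-like and -0.43 in PrE-like cells. Mural trophectoderm genes were 0.83 in TE-like and -0.40 in PrE-like cells, and 0.40 and -0.50 over Type II. With both clusters weighted equally, neither list stood apart in PrE-like cells (TE markers 0.02 and -0.07, mural genes 0.18 and -0.005 over Types I and II), nor did TE markers in EPI-like cells (0.04), so these oppositions depend on the clusters. Parietal endoderm genes were 0.29 in PrE-like and -0.19 in TE-like cells, but the TE-like value was 0.24 with a minimum of 10 CPM, so this opposition depends on the processing. G2 and M phase genes in Type II over Type I were 0.10 in EPI-like, -0.09 in PrE-like and -0.13 in TE-like cells, and with equal weights they did not stand apart in EPI-like cells (-0.001).

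Xist, the RNA of the inactive X chromosome, gave a signal in data outside the comparisons. PrE-like cells with at least 10000 UMIs held 832 Xist UMIs, of which 758 (91.1%) were in 10 of 1588 cells, 7 from Type I and 3 from Type II. The highest cell had 213, against at most 4 in a cell of the other classes in the comparison. Of the 10 cells 7 also had Y gene UMIs, at 46.3 CPM against 44.8 CPM in the remaining PrE-like cells.

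The lower PrE-like share of Type III could be technical if shallow barcodes, joint clustering or the naming rule removed PrE-like cells. Among barcodes with at least 10000 UMIs the share was still 0.371 of that in Type I, and 0.425 with each library clustered alone. The share of deep barcodes with UMIs of 2 of Gata6, Sox17 and Gata4, which needs no clusters, was 23.2% against 49.7%, a ratio of 0.466. For deep barcodes these values argue against the 3 causes. With each library clustered alone and all barcodes counted, the ratio was 2.62 (37.83% against 14.4%), so for the share of all barcodes joint clustering and naming stay open.

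Pou5f1, Utf1 and Dppa5a were higher in PrE-like cells of Type III, and EPI-like genes as a group in its TE-like cells. Both could come from epiblast RNA in the droplets. In PrE-like cells 58.2% of 55 EPI-like genes were higher, with a median excess of 0.112% of the EPI-like level. Pou5f1 had 12.6%, Utf1 10.4% and Dppa5a 16.7%, but Nanog -0.153% and Tdgf1 -0.693%. This uneven excess argues against RNA in the droplets as the cause in PrE-like cells. Without the 5 cells with most Pou5f1 its log2 ratio was still 1.32. The lower of the Pou5f1 ratios within the 2 PrE-like clusters was -0.17 (cluster 2) and the other 0.54 (cluster 10), but Pou5f1 was among the genes that made the clusters. Utf1, also among them, had 0.13 and 0.39, so for both genes whether another mix of clusters is the cause stays open. Dppa5a was not among those genes, and its ratios were 0.07 and 0.06. This fits another mix for Dppa5a, but its values were taken after the result was seen and, as given below, its level is uncertain. In TE-like cells 100% of 34 EPI-like genes were higher, with a median excess of 5.50%, which taken alone would fit RNA in the droplets. Utf1 at 23.6%, Dppa5a at 19.4% and Dppa3 at 16.8% lay above it. RNA shared by all droplets would also reach PrE-like cells of that library, whose median excess over their own 55 genes was 0.112%. Deep barcodes of Type III had similar median UMI counts in both classes (94178.5 PrE-like, 80681 TE-like). The cause in TE-like cells therefore stays open. The visceral endoderm median in PrE-like cells went to 0.26 with equal weights, but the clusters were made from these genes too, so a change of mix and a loss of these transcripts cannot be told apart.

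Of 24 genes shifted alike in all 3 classes of Type III, 17 have a near-identical copy (70.8%), against a median of 12.5% and at most 37.5% in random sets matched on expression. This fits reads shared with copies, which may be assigned differently when read length differs between libraries. Eno1, Dppa5a and Gapdh are therefore uncertain. Glycolysis in Type III over Type I, without Eno1, Gapdh and Gpi1, still stood apart in 3 of 3 classes (0.35, 0.40 and 0.43), so copies do not account for it. Over Type II it stood apart only in PrE-like cells, and Type II over Type I was as high in EPI-like (0.35) and TE-like cells (0.40), so there it is not a trait of Type III.

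Relabelling the 6 sums of each class comparison gives 10 splits, too few for a share under 0.05. The real split, 1 of 10 each, gave 276, 270 and 239 genes, and the highest other gave 0. These counts come from fits of only the 2 classes compared, so they differ from those of the joint fit. Every other split mixes the 2 classes within its groups, which puts the class difference into the spread. A low count was therefore largely fixed in advance and does not measure chance.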

How the results depend on the processing

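Only barcodes with at least 10000 UMIs, such barcodes clustered on their own or alone, and equal cluster weights were tests chosen only after seeing the data. Readout gene counts of the class comparisons kept their size under every setting, and with 1 library left out they ranged from 252 to 281 (PrE-like over EPI-like), 229 to 270 (TE-like over EPI-like) and 216 to 261 (PrE-like over TE-like). The cause was not tested for any value below, unless stated. The strict filter and the limit of 10000 UMIs leave under 50 PrE-like cells in Type III (49 and 48), so those pairs of libraries were not run. The class comparisons in these 2 settings were run without the PrE-like sum of Type III. Without library as a block, the class comparisons had 260, 242 and 227 readout genes in the same order.

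Shares are in percent. At resolution 0.5, EPI-like in Type I was 10.55 and TE-like 16.53, 12.92 and 27.99 (Types I, II and III). No cluster was named primed epiblast-like there, and the UMIs of TE-like cells in Type I went from 13649147 to 24339999. TE-like values at resolution 0.5 may therefore include primed epiblast-like cells, which was not tested. At resolution 2, EPI-like was 6.652, 7.789 and 11.28, PrE-like 27.78, 20.4 and 12.21, and TE-like in Type I 11.78. With the strict filter, which leaves deeper barcodes, EPI-like was 12.02, 15.39 and 23.04, PrE-like 33.3, 28.51 and 10.36, and TE-like 14.09, 12.02 and 21.14. With each library clustered alone, EPI-like was 4.296, 4.139 and 7.125, and in Type III PrE-like 37.83 and TE-like 27.82. With 4000 variable genes, EPI-like in Types I and II was 12.31 and 12.74, and PrE-like 29.86, 24.38 and 13.74. With only barcodes of at least 10000 UMIs, EPI-like was 14.82, 17.53 and 29.78, PrE-like 47.63, 44.37 and 17.65, and TE-like 17.84, 15.66 and 28.31, and 8 lists stood apart in EPI-like Type II over Type I. Such barcodes clustered on their own gave EPI-like 14.39, 16.02 and 26.47, PrE-like 48.49, 44.92 and 19.12, and TE-like in Type II 11.07. Each library alone with such barcodes gave EPI-like 13.96, 15.72 and 24.63, PrE-like 47.63, 44.47 and 20.22, and TE-like 17.84, 15.92 and 40.81.

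With the mean of per-cell CPM, which gives shallow barcodes equal weight, whole Type II over Type I had 0 genes and 9 lists apart. EPI-like cells had 7 lists in II over I, 13 genes in III over I, and 15 genes and 10 lists in III over II. TE-like cells had 1 gene and 7 lists in II over I. AY036118 in PrE-like III over I reversed to 0.28, Atp1b1 in TE-like III over I to -0.0887 and Phlda2 in TE-like III over II to -0.011.

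With a minimum of 10 CPM, which admits more genes, whole libraries had 62 (III over I) and 41 (III over II) genes apart, EPI-like cells 1, 7 and 16 genes and 16, 19 and 12 lists (II over I, III over I, III over II), PrE-like cells 34 genes in III over I, and TE-like cells 49 and 26 genes over Types I and II. Parietal endoderm in TE-like cells reversed to 0.13 (II over I) and 0.24 (III over I). With no minimum these were 62 and 41, then 1, 7 and 16 genes and 15, 17 and 13 lists, 34, and 49 and 26, with 17 lists in TE-like III over I. With mitochondrial and ribosomal genes left out of the total, EPI-like cells had 1, 9 and 16 genes and 12, 15 and 11 lists.

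With both clusters weighted equally, EPI-like cells had 1 gene and 9 lists in II over I, and 15 genes and 10 lists in III over II. PrE-like cells had 3 genes in III over I, and 6 genes and 6 lists in III over II. TE-like cells had 3 genes in II over I and 17 in III over I. In PrE-like cells imprinted genes reversed to 0.20 (III over I) and 0.16 (III over II), and visceral endoderm to 0.26 (III over I).

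With classes from resolution 0.5, EPI-like cells had 9 lists and TE-like cells 1 gene in II over I, EPI markers in TE-like III over II reversed to -0.15, and Pmaip1 in TE-like over EPI-like cells to 0.22 (adjusted p = 0.152). With classes from resolution 2, EPI-like cells had 7 lists in II over I, and TE-like cells 2 genes and 9 lists in II over I and 16 genes in III over I. With 1 CPM added, PrE-like III over I had 32 genes.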

Other observations

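The tests of single genes within the PrE-like clusters, apart from Pou5f1, were chosen only after the result was seen.

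The 2 PrE-like clusters had different levels of 2 pluripotency genes and 2 visceral endoderm genes. In Type I, cluster 10 held Pou5f1 at 116 CPM against 9.74 CPM in cluster 2, and Utf1, a chromatin factor of pluripotent cells, at 77.4 against 20.6 CPM. Rbp4 was 51.2 against 1459 CPM and Apoa2 4.76 against 452 CPM. Ckb was 276 against 29.1 CPM. These genes were chosen after their values were seen, and the clusters were made from the same data, so no test was made between them.

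EPI-like cells of Type II had higher glycolysis (median log2 0.36) and cholesterol synthesis and uptake (0.18) than those of Type I, with no single gene 2-fold apart. In PrE-like cells Type II was higher in Ckb (0.67), in the water channel gene Aqp8 (0.52) and in Apoa1 (0.48), a lipid carrier.

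Within the PrE-like clusters the ratios of Type III over Type I were -0.17 (cluster 2) and 0.54 (cluster 10) for Pou5f1, -0.19 and -0.80 for Rbp4, -0.18 and -0.23 for Apoa2, and 0.54 and 0.82 for Ckb. For Utf1 they were 0.13 and 0.39, and for Dppa5a 0.07 and 0.06. Cluster 10 held 46.4% of the PrE-like cells of Type III. No time course was used here to order the clusters.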
